A study of Homo sapiens with 13 samples.

How the data were processed

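RNA from 13 samples of the NCI-H660 and V16D prostate cancer lines was labelled with Cy3 and hybridised to Agilent SurePrint G3 Human v3 arrays, 1 sample per array and 1 colour. Per the file headers, the scanner files hold background-subtracted spot intensity values made with Agilent Feature Extraction 11.0.1.1, with no normalization between arrays. The deposited value table holds log2 values. Its columns share a median of 5.15 in every NCI-H660 array and 4.63 in every V16D array, and at 9 percentiles from 1 to 99 the arrays of a line differed by at most 0.0016 and 0.00426, against up to 1.15 and 1.41 in the scanner files. Arrays of a line thus had nearly the same distribution in that table, as after quantile normalization. The labels do not state how that table was made. Its direction matched that of the scanner files (r across probes 0.998 to 1.00), and it served only as an alternative.

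Each array had 62976 spots, of which 60901 were not controls. Between 43 and 95 spots per array were left out because the scanner software called them outliers, no spot was saturated, and repeat spots of a probe were averaged, which left 58201 probes. A gene symbol was found for 31104 probes (53.4%) and none for 27097, and the former covered 22439 genes. Where a gene had several probes (6754 genes), the probe with the highest mean over the arrays of the fit was used. Signals were set to log2, and each array's 75th percentile was subtracted. A probe counted as well above background on an array when at least a share of 0.5 of its spots did. Genes well above background on every array of at least 1 group of a fit were tested, and 12 genes in NCI-H660 and 18 in V16D with a missing value were left out. This left 18035 genes in NCI-H660 and 18147 in V16D. The share of probes well above background ran from 59.0% to 69.2% per array, and the small number of arrays limits the precision.

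The 5 NCI-H660 arrays were fitted apart from the 8 V16D arrays, since the lines lay on separate slides and may differ in spread. Comparisons were knockdown minus control in NCI-H660 cells and, in V16D cells, HP1α vector minus control vector in each medium, enzalutamide medium minus complete medium with each vector, and the difference between the 2 effects of the vector. Linear models with moderated variances were fitted in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Values after ± are standard errors (SE) of a log2 fold change from limma unless SD is written. Principal components were computed for each line over the genes tested, centred and unscaled. The residual degrees of freedom were 3 in NCI-H660 and 4 in V16D. Fold changes against a group whose arrays were not well above background are given as lower bounds, computed with the dim group at the lowest level that counts as above background.

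Before the data were examined, 20 gene lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed. The lists were heterochromatin factors, neuroendocrine markers, REST-repressed neuronal genes, androgen-induced and androgen-repressed genes, luminal, basal and mesenchymal markers, mitosis genes, DNA replication genes, interferon-stimulated genes, ATF4 and unfolded protein response genes, p53 targets, cholesterol synthesis genes, hypoxia genes, zinc finger genes with a ZNF name, clustered protocadherins, cancer-testis genes, fibroblast markers, and leukocyte and endothelial markers. Each list was tested against the other genes with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, with adjustment over the lists of a comparison. Lists with under 5 tested members got counts only. Members were also counted with p-values adjusted over the list alone. Of the neuroendocrine markers, 8 were also in the list of REST-repressed genes.

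The rule named, among others, CBX5, CBX1, CBX3, REST, KLK3, TMPRSS2, SYP, CHGA, ENO2, NCAM1, SOX2 and EZH2 in every comparison. It added the 6 largest rises and 6 largest falls per comparison (4 and 4 for the difference of effects) among genes past the threshold whose arrays did not overlap between groups, and up to 4 members with the smallest p in each list. Symbols of uncharacterised loci, long non-coding and micro-RNA genes were passed over, as were XIST and genes on the Y chromosome, which were left out throughout. Genes named outside that rule are said to have been chosen after their values were seen.

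The code was tested on simulated data made by planting 200 changed genes, 50 of each size, on the residual spread of each fit. In NCI-H660, 107 planted genes and 4 others were called, and 4%, 40%, 78% and 92% of the genes planted at 1.5-fold, 2-fold, 4-fold and 8-fold were found. V16D was simulated for enzalutamide medium in control-vector cells. There, 58 planted genes and 5 others were called, and 0%, 4%, 44% and 68% were found. The real comparison had 8096 calls, and more changed genes loosen the Benjamini-Hochberg cut, so these rates do not give its recovery. A planted list of 30 shifted genes was called by camera in both lines, and no unchanged list was. Noise was drawn independently for each gene, so the simulation does not test camera on lists whose members vary together. In NCI-H660 the controls were simulated as separate samples at the pooled spread, so its rates of recovery rest on that assumption.

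Alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter asking for signal on every array, the mean of all probes of a gene, all 13 arrays in 1 fit, only the groups compared, a variance trend with a robust prior, replicate number as a block, the deposited value table, an estimated correlation for lists, and leaving out each array in turn. Slide row as a block, replicate number as a block within each medium, averaged NCI-H660 controls, and leaving out both complete-medium arrays of 1 number were added after the data were seen. Responses were compared across genes by Pearson's r and by the overlap of calls, where the filter and, for calls, a change of at least 1.5-fold were varied.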

Results

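Transcript levels were measured on 13 one-colour arrays in 2 human prostate cancer cell lines whose level of HP1α, the heterochromatin protein encoded by CBX5, had been lowered or raised. NCI-H660 is a neuroendocrine prostate cancer line, and V16D is a castration-resistant line derived from LNCaP. NCI-H660 cells carried a control lentivirus (2 arrays) or a lentivirus delivering short hairpin RNA against HP1α (3 arrays). V16D cells carried a control or an HP1α vector and were kept for 14 days in complete medium with fetal bovine serum, or were starved for 24 h in charcoal-stripped serum and then kept for 14 days with 10 µM enzalutamide, an antiandrogen, with 2 arrays in each of the 4 groups. Serum and drug differed together between the media and cannot be told apart. Between 59.0% and 69.2% of probes were well above background on each array, and the 75th percentile of signal ran from 265 to 419. Values below are log2 units relative to that percentile. The labels give each knockdown sample the prefix sh and a number of its own, while the controls carry replicate numbers. They do not state whether the knockdown numbers stand for separate hairpins. If so, each hairpin had 1 array and the spread includes differences between hairpins. Nor do the labels say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The NCI-H660 control arrays differed by less than repeat spots of a probe would (SD of the difference 0.0656, against 0.0752 and 0.0871 for repeat spots), so they stand for 1 sample and their mean is given without SD. The fit fixed beforehand used both as arrays, and its SE and p-values are those given for the knockdown. If both arrays hold 1 sample, these SE and p-values are too small. Counts adjusted over a list alone were not repeated with the controls averaged.

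CBX5 was measured by 2 probes, one annotated to transcript NM_001127322 and the other to NM_012117. In NCI-H660 cells the former read 5.00 and 5.04 on the control arrays and 2.47, 3.76 and 3.03 on the knockdown arrays, or 17.1%, 41.7% and 25.1% of the control mean. The latter read 2.82 and 2.84 on the control arrays and 0.03, 1.37 and 0.80 on the knockdown arrays, or 14.3%, 36.3% and 24.5%. In V16D cells the NM_012117 probe read 2.35 and 1.58 with the control vector and 5.07 and 5.35 with the HP1α vector in complete medium, a difference of 3.25 ± 0.32 (9.49-fold; adjusted p = 0.235 over all probes). In enzalutamide medium it read 0.78 and 0.76 with the control vector and 3.51 and 3.92 with the HP1α vector, a difference of 2.95 ± 0.32 (7.71-fold; adjusted p = 0.299 over all probes). The brighter NM_001127322 probe read 4.20 and 3.76, against 3.97 and 3.52 with the HP1α vector, in complete medium, and 3.06 and 3.16, against 3.09 and 3.18, in enzalutamide medium. That probe was the one used in the fits and does not register the vector, so CBX5 values of the V16D fits cover the transcripts it detects.

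**Figure D1:**
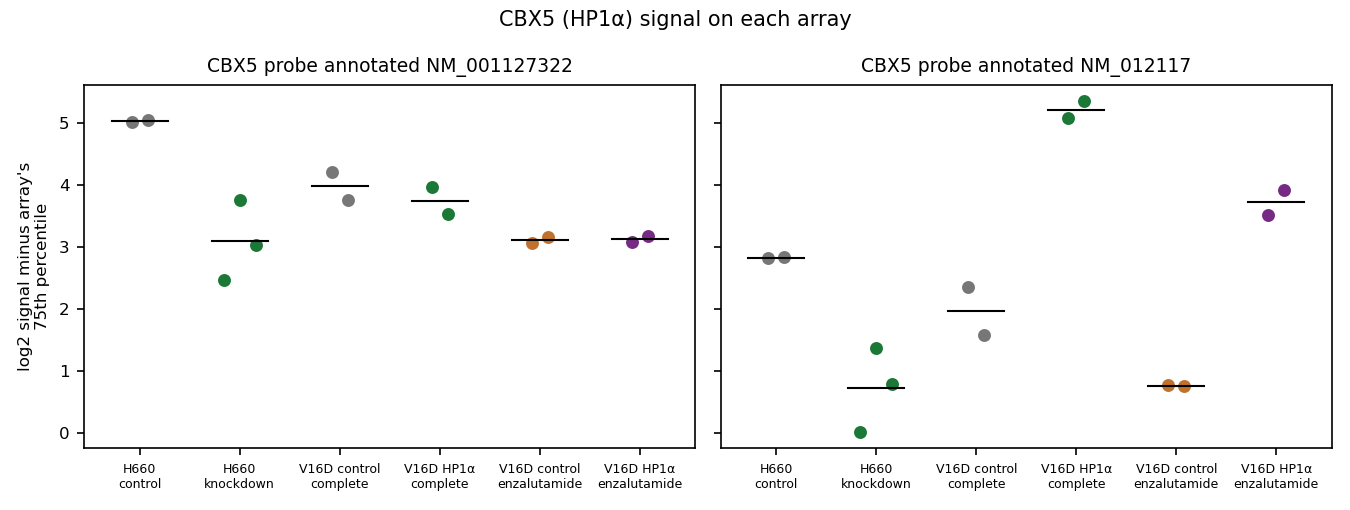
Log2 signal of the 2 CBX5 probes relative to each array's 75th percentile (y) in the 6 groups (x), with dots for arrays and black lines for group means. Both probes lie below both controls on all 3 knockdown arrays, and only the NM_012117 probe is higher with the HP1α vector (5.21 against 1.96 in complete medium, 3.72 against 0.77 in enzalutamide medium).

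Marker genes set the 2 lines apart in their control arrays. NCI-H660 cells had high CHGA (7.10), encoding the secretory granule protein chromogranin A, NCAM1 (4.74), a neural adhesion gene, and SOX2 (4.21), a neural stem cell factor gene. SYP, which encodes synaptophysin, read −0.32 there, and ENO2, encoding neuron-specific enolase, read 2.72. In V16D control cells in complete medium, NCAM1 and SYP were not well above background, CHGA and SOX2 were above it on 1 of 2 arrays, and ENO2 read 0.45 ± 0.17 (SD, n = 2). KLK3, which encodes prostate-specific antigen, read 9.13 ± 0.15 (SD) in V16D cells and was not above background in NCI-H660 controls. TMPRSS2, an androgen-regulated protease gene, read 5.47 ± 0.30 (SD) in V16D and −2.15 in NCI-H660 cells. REST, the repressor of neuronal genes, read 0.10 ± 0.35 (SD) in V16D and −2.08 in NCI-H660, and EZH2, a histone methyltransferase gene, 2.35 ± 0.98 (SD) and 3.97. Each line lay on its own slide, so line and slide cannot be told apart and no test was made.

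The knockdown asked which transcripts of a neuroendocrine line depend on HP1α. CBX5 was 3.82-fold lower in the knockdown arrays (−1.93 ± 0.36; n = 3 against 2 control arrays; adjusted p = 0.235), and with the controls averaged to 1 sample the unadjusted p was 0.0084 and the adjusted p 0.9997. The other HP1 genes CBX1 and CBX3 read 0.11 ± 0.16 and 0.13 ± 0.17 relative to control. Neuroendocrine genes stood close to control, with CHGA at −0.04 ± 0.11, SYP at −0.03 ± 0.19, NCAM1 at −0.08 ± 0.20, ENO2 at 0.22 ± 0.16 and SOX2 at 0.09 ± 0.12. REST (−0.29 ± 0.15), EZH2 (0.05 ± 0.19) and TMPRSS2 (−0.01 ± 0.14) did not pass the test either. KLK3 was above background on knockdown arrays 2 and 3 alone (−2.66 and −3.82), so it was not tested. limma called 0 of 18035 genes, with a smallest adjusted p of 0.210, and 2405 had an unadjusted p under 0.05 (1110 higher, 1295 lower). With the controls averaged to 1 sample the counts were 0 and 521. Without knockdown array 1, limma again called 0 and 5288 genes had an unadjusted p under 0.05. The knockdown arrays were not alike, since on principal component 1 (45.3% of variance) array 1, with the lowest CBX5, scored −21.4, near the controls (−17.9 and −17.3), and arrays 2 and 3 scored 27.5 and 29.1. On component 2 (30.4%) array 1 lay farthest from the controls (−33.0 against 17.6 and 17.9), with arrays 2 and 3 at 4.98 and −7.48. Chosen after their values were seen, NKX2-2 (1.80 ± 0.38), a neuroendocrine homeobox gene, NR2F1 (1.54 ± 0.20), an orphan nuclear receptor gene, and FST (1.47 ± 0.18), which encodes follistatin, were among the largest positive differences. SLC2A4 (−1.78 ± 0.29), encoding the glucose transporter GLUT4, and RDM1 (−1.62 ± 0.30), a gene linked to DNA repair, were among the largest negative ones.

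Of the lists, the mitosis genes had 27 of 27 tested members below control after knockdown, with a median of −0.30 and CDK1 (−0.47 ± 0.15), the mitotic kinase gene, ASPM (−0.45 ± 0.11), a spindle gene, and BUB1 (−0.40 ± 0.13), a spindle checkpoint gene, as examples. None of them passed over all genes, and 0 did adjusted over the list alone. camera called the list lower (adjusted p = 1.22e-05; adjusted p = 0.770 with an estimated correlation), with medians of −0.14, −0.21 and −0.57 on the 3 knockdown arrays. ATF4 and unfolded protein response genes had 20 of 21 members below control (median −0.38), among them HSPA5 (−0.82 ± 0.15), encoding the endoplasmic reticulum chaperone BiP, PDIA4 (−0.63 ± 0.19), encoding a disulfide isomerase, and HERPUD1 (−0.54 ± 0.17). camera called that list lower (adjusted p = 1.22e-05; adjusted p = 0.770 with an estimated correlation), with medians of −0.19, −0.27 and −0.69 on the 3 knockdown arrays, and 1 member passed adjusted over the list alone. Without knockdown array 3 the mitosis and ATF4 medians shrank to −0.19 and −0.24, with both calls kept. Of 31 neuroendocrine markers, 21 were above control (median 0.09) and 2 passed, both higher, adjusted over the list alone. They included NEUROD1 (1.24 ± 0.18), a neural bHLH factor gene, SYT1 (0.79 ± 0.14), encoding a vesicle calcium sensor, PEG10 (0.95 ± 0.23) and GRP (0.91 ± 0.22), encoding gastrin-releasing peptide. camera called these markers higher (adjusted p = 0.0297; adjusted p = 0.467 with an estimated correlation), and the call was lost without knockdown array 1 (median 0.08). Hypoxia genes were not called as a list (adjusted p = 0.432), and 4 members passed adjusted over the list alone, ADM (1.05 ± 0.13) higher and ALDOC (−0.91 ± 0.11), VEGFA (−0.88 ± 0.14) and NDRG1 (−0.58 ± 0.11) lower. Heterochromatin factors (median 0.04), REST-repressed genes (0.05) and androgen-induced genes (0.04) were not called, nor were the other lists tested, with adjusted p from 0.0908 to 0.927 and 0 members adjusted over the list alone. Androgen-repressed genes had 4 tested members, all positive (median 0.42), too few for a list test. The calls of mitosis genes and neuroendocrine markers were lost with all 13 arrays in 1 fit, the latter also under normexp correction and under either other filter, while without knockdown array 3 the clustered protocadherins (median −0.16) and zinc finger genes (−0.08) were called lower.

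Raised HP1α in V16D cells in complete medium was compared with the control vector to ask what HP1α changes in cells with androgen signalling. Androgen-induced genes stood near control, with KLK3 at −0.28 ± 0.36 and TMPRSS2 at −0.31 ± 0.34 (2 arrays against 2). ENO2 was at −0.54 ± 0.26, REST at −0.04 ± 0.30, EZH2 at −0.01 ± 0.68, CBX1 at 0.08 ± 0.19 and CBX3 at 0.27 ± 0.52. NCAM1 was at background with both vectors, and CHGA, SYP and SOX2 were too dim to test. Of 18147 genes, limma called 0 higher and 3 lower, RDH16 (−3.18 ± 0.21), a retinol dehydrogenase gene, GUCA1B (−2.91 ± 0.22), a guanylate cyclase activator gene, and LINC02362 (−3.01 ± 0.23), a non-coding gene outside the naming rule that was chosen after its value was seen (each adjusted p = 0.0308). At an unadjusted p under 0.05 there were 325, or 1.79% of the genes tested, below the share of 0.05 that no change would give. With replicate number as a block within each medium there were 1416, and 5 were called, RDH16 and GUCA1B among them and LINC02362 not. RDH16 was also at −1.93 ± 0.21 in enzalutamide medium, where it did not pass. For GUCA1B and LINC02362 a second probe was at background in V16D cells, and both calls were lost under normexp correction and with the mean of all probes. The 3 calls were lost without control array 2 in complete medium and without any 1 of the enzalutamide arrays, and the count was 14 and 4 without control arrays 1 and 2 and 43 and 15 without HP1α arrays 1 and 2 in complete medium. LINC02362 was also lost without HP1α array 2. With no filter on dim probes, only the groups compared, or replicate number as a block it was 0. Chosen after their values were seen, the cancer-testis genes MAGEC2 (2.56 ± 0.39) and MAGEC1 (2.12 ± 0.26) and PIP (3.51 ± 0.53), a secreted protein gene, were higher without passing, and S100A1 (−2.70 ± 0.26) was lower without passing.

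The complete-medium arrays numbered 1 and 2 also differed from each other alike with either vector. On array 2, 27 of 27 mitosis genes were lower (median −4.31 with the control and −3.72 with the HP1α vector) and 28 of 28 DNA replication genes were lower (−2.56 and −2.34), as in MKI67, a proliferation marker gene, at −1.63 and −1.24 against 1.69 and 1.69 on array 1. Cholesterol synthesis genes were lower in 20 of 23 (−0.65 and −0.90), while p53 targets were higher in 17 of 23 (0.44 and 0.38), clustered protocadherins in 27 of 37 (0.66 and 0.47) and ATF4 genes in 14 of 21 (0.44 and 1.00).

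With raised HP1α in complete medium, camera called 4 lists. Cancer-testis genes were called higher (19 of 25 positive, median 0.08, adjusted p = 0.00144; adjusted p = 0.499 with an estimated correlation), with MAGEC1, MAGEC2 and MAGEC3 (1.19 ± 0.29) as the 3 members that passed adjusted over the list alone, all higher. p53 targets were called higher (21 of 23 positive, median 0.29, adjusted p = 5.95e-05; adjusted p = 0.621 with an estimated correlation), with CDKN1A (0.74), encoding the cell cycle inhibitor p21, and BTG2 (0.56), an antiproliferative gene, as examples. Clustered protocadherins, neural adhesion genes, were called higher (31 of 37 positive, median 0.18, adjusted p = 0.00727; adjusted p = 0.922 with an estimated correlation). ATF4 genes were called lower (16 of 21 negative, median −0.22, adjusted p = 0.0214; adjusted p = 0.683 with an estimated correlation), with CHAC1 (−1.32), a glutathione-degrading enzyme gene, as an example. In the latter 3 lists 0 members passed adjusted over the list alone or over all genes. The mitosis genes were positive in 27 of 27 (median 0.33) and not called (adjusted p = 0.638), but with replicate number as a block within each medium they and DNA replication genes (median 0.21) were called higher (adjusted p = 3.09e-07 and 0.00185). An estimated correlation was not run with that block, and in the main fit camera with it gave adjusted p = 0.969 for each of these lists. The other lists were not called either (adjusted p from 0.0611 to 0.932), and among them 1 leukocyte or endothelial marker passed adjusted over the list alone, higher. Leaving out 1 complete-medium array ended each call. The cancer-testis call was lost without HP1α array 1 (median −0.02) and with only the groups compared (0.06), the p53 call without control array 1 (0.08) or HP1α array 2 (0.12), the protocadherin call without control array 1 (−0.12) or HP1α array 2 (0.03), and the ATF4 call without control array 1 (−0.53), control array 2 (−0.09) or HP1α array 1 (0.28).

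Enzalutamide medium was compared with complete medium in control-vector cells to follow the response to loss of androgen signalling, which the study used to induce a neuroendocrine state. Androgen-induced genes fell, with KLK3 52.6-fold lower (−5.72 ± 0.36, n = 2 against 2), TRPM8, a cold-sensing channel gene, at −5.33 ± 0.31 and TMPRSS2 13.5-fold lower (−3.76 ± 0.34). Of the neuroendocrine genes, ENO2 rose 3.08-fold (1.63 ± 0.26), and NCAM1 and CHGB, encoding chromogranin B, rose at least 2.31-fold and at least 3.06-fold, since neither was above background in complete medium. REST (−0.44 ± 0.30) and EZH2 (−0.92 ± 0.68) did not pass, and CHGA, SYP and SOX2 were too dim to test. The HP1 genes fell, CBX1 by 1.76 ± 0.19, CBX3 by 2.21 ± 0.52 and CBX5 by 0.87 ± 0.24 on the probe of the fit and 1.19 ± 0.32 on the NM_012117 probe (adjusted p = 0.0354 over all probes). The largest falls included ST6GALNAC1 (−7.98 ± 0.50), a sialyltransferase gene, MSMB (−7.40 ± 1.11), encoding a secreted prostate protein, and TM4SF1 (−6.87 ± 0.76), and the largest rises MID1 (at least 42.2-fold), a ubiquitin ligase gene, CDH18 (6.15 ± 0.37), a neural cadherin gene, and SEMA5A (5.68 ± 0.57), an axon guidance gene.

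In all, limma called 3395 genes higher and 4701 lower of 18147 in control-vector cells in enzalutamide medium, of which 2458 and 3499 changed at least 2-fold. The median of all genes was −0.11 there (−0.12 with the HP1α vector) and moved by less than 0.1 under quantile normalization (−0.10), and 553 of the calls were at background in 1 of the groups. The count was 4637 and 5023 without control enzalutamide arrays 2 and 1 and 5054 without control array 1 in complete medium. The CBX5 and CBX3 calls were lost under quantile normalization (−0.34 and −1.52) and without control array 1 in complete medium (−0.65 and −1.57) or control enzalutamide arrays 1 (−0.82 and −2.37) or 2 (−0.92 and −2.05), and the CBX5 call also without HP1α enzalutamide array 1 or 2 (−0.87 in each), with all 13 arrays in 1 fit (adjusted p = 0.0629) and with only the groups compared (adjusted p = 0.0589). The NCAM1 call was lost under normexp correction (0.38).

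**Figure D2:**
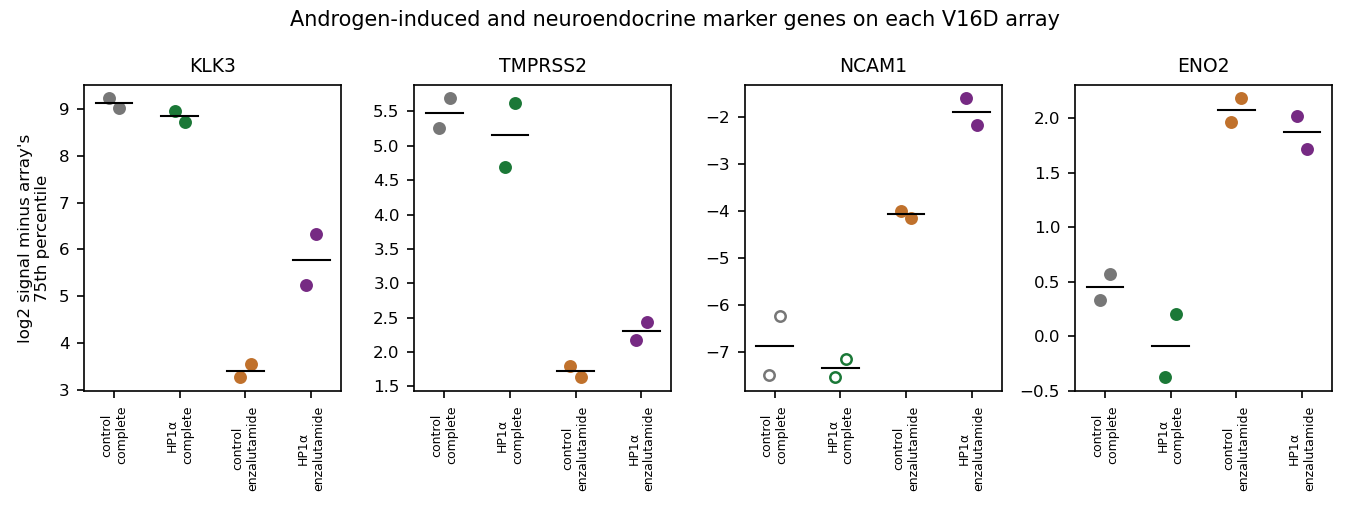
Log2 level relative to each array's 75th percentile (y) of KLK3, TMPRSS2, NCAM1 and ENO2 on each V16D array in the 4 groups (x), with open dots for arrays on which the gene was not well above background. KLK3 lies at 3.26 and 3.56 with the control vector and 5.23 and 6.33 with the HP1α vector in enzalutamide medium, against 8.72 to 9.23 in complete medium.

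Gene groups moved as follows in control-vector cells in enzalutamide medium. Androgen-induced genes fell in 27 of 34 and rose in 0 (median −2.25; camera adjusted p = 3.18e-09; adjusted p = 0.108 with an estimated correlation; 29 lower adjusted over the list alone). HERC3 (−3.05 ± 0.25) and HOMER2 (−2.46 ± 0.19) were among those that fell. Clustered protocadherins rose in 24 of 37 and fell in 0 (median 1.00; adjusted p = 8.16e-08; adjusted p = 0.367 with an estimated correlation; 27 higher adjusted over the list alone). PCDHA3 (1.92 ± 0.23) and PCDHGB4 (1.41 ± 0.23), neural adhesion genes, were among them. ATF4 and unfolded protein response genes fell in 13 of 21 (median −2.02; adjusted p = 0.00114; adjusted p = 0.367 with an estimated correlation; 14 adjusted over the list alone). The stress response genes ATF3 (−3.76 ± 0.43) and TRIB3 (−3.63 ± 0.48) were examples. p53 targets fell in 12 of 23 and rose in 1 (median −1.15; adjusted p = 0.00386; adjusted p = 0.401 with an estimated correlation; 14 lower and 1 higher adjusted over the list alone). CCNG1 fell by 2.19 ± 0.20 and TRIAP1 by 2.16 ± 0.21. Hypoxia and glycolysis genes fell in 10 of 18 (median −1.39; adjusted p = 0.00422; adjusted p = 0.239 with an estimated correlation; 10 adjusted over the list alone). NDRG1 fell by 3.15 ± 0.27 and the mitophagy gene BNIP3 by 2.47 ± 0.20. Fibroblast markers rose in 5 of 7 and fell in 1 (median 1.91; adjusted p = 0.0171; adjusted p = 0.293 with an estimated correlation; the same counts adjusted over the list alone). The collagen genes COL5A1 (1.91 ± 0.21) and COL1A1 (2.06 ± 0.32) were higher. REST-repressed neuronal genes rose in 9 of 20 and fell in 2 (median 0.91; adjusted p = 0.0244; adjusted p = 0.401 with an estimated correlation; 9 and 2 adjusted over the list alone). GDAP1 (1.88 ± 0.25) and KIF1A (1.26 ± 0.18), a neuronal kinesin gene, rose, and VGF (−2.67 ± 0.21), a neuropeptide precursor gene, fell. Basal markers rose in 6 of 11 (median 0.92; adjusted p = 0.0309; adjusted p = 0.293 with an estimated correlation; 6 adjusted over the list alone). ITGB4, an epithelial integrin gene, rose by 3.08 ± 0.28.

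The remaining lists were not called by camera in control-vector cells in enzalutamide medium. Neuroendocrine markers rose in 7 of 19 and fell in 3 (adjusted p = 0.0816; 7 and 3 adjusted over the list alone). Androgen-repressed genes rose in 2 of 5 (adjusted p = 0.0816; 3 adjusted over the list alone), OPRK1 (3.50 ± 0.44), an opioid receptor gene, and UGT2B15 (3.89 ± 0.57), encoding an androgen-conjugating enzyme. Luminal markers fell in 7 of 17 and rose in 2 (adjusted p = 0.138; 7 and 3 adjusted over the list alone). KRT18 (−1.71 ± 0.19), a keratin gene, and SPDEF (−1.47 ± 0.20), a luminal transcription factor gene, fell. Mesenchymal markers rose in 7 of 16 and fell in 3 (adjusted p = 0.168; 7 and 3 adjusted over the list alone). The matrix genes TNC (2.78 ± 0.24) and FN1 (2.46 ± 0.39) rose. Mitosis genes passed in 0 of 27 (median −1.0; adjusted p = 0.594) and DNA replication genes in 0 of 28 (median −1.26; adjusted p = 0.104), over all genes and adjusted over the list alone, and, like the protocadherins, p53 targets and ATF4 genes, they differed between the complete-medium arrays as given above. Heterochromatin factors fell in 6 of 30 (adjusted p = 0.138; 1 adjusted over the list alone), cholesterol synthesis genes in 3 of 23 (adjusted p = 0.104; 0 adjusted over the list alone), and zinc finger genes in 93 of 474 with 45 higher (adjusted p = 0.441; 65 and 33 adjusted over the list alone). Interferon-stimulated genes rose in 2 of 26 and fell in 3 (adjusted p = 0.995; 1 and 2 adjusted over the list alone), cancer-testis genes rose in 5 of 25 and fell in 7 (adjusted p = 0.898; 5 and 8 adjusted over the list alone), and leukocyte and endothelial markers rose in 3 of 10 and fell in 1 (adjusted p = 0.0816; 3 and 1 adjusted over the list alone). The REST-repressed call was lost without control array 1 in complete medium (median 0.59) or control enzalutamide array 2 (0.82) and with no filter or all 13 arrays in 1 fit, the basal call without control enzalutamide array 1 (0.75) or HP1α enzalutamide array 2 (0.88), under quantile normalization and with no filter, and the fibroblast call with no filter (median 0.383). Under normexp correction the calls of fibroblast markers, REST-repressed genes and basal markers held with smaller medians (0.43, 0.39 and 0.536).

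In HP1α cells the same change of medium asked whether raised HP1α altered that response. KLK3 fell 8.38-fold (−3.07 ± 0.36, n = 2 against 2) and TMPRSS2 by 2.86 ± 0.34. NCAM1 rose at least 9.59-fold and CHGB at least 3.10-fold from background, and ENO2 rose by 1.96 ± 0.26. REST (−0.48 ± 0.30), EZH2 (−0.83 ± 0.68) and CBX5 on the probe of the fit (−0.61 ± 0.24) did not pass, and CBX1 fell by 1.43 ± 0.19 and CBX3 by 2.06 ± 0.52. The NM_012117 probe, which also registers the vector, fell by 1.49 ± 0.32 (adjusted p = 0.0262 over all probes), and with only the groups compared CBX5 was read from it and passed (adjusted p = 0.0224). The largest falls included ST6GALNAC1 (−7.93 ± 0.50), PIP (−6.56 ± 0.53) and ELOVL2 (−6.41 ± 0.54), a fatty acid elongase gene, and the largest rises SEMA5A (6.75 ± 0.57), IGFBP3 (6.74 ± 0.41), encoding an insulin-like growth factor binding protein, and MID1 (at least 49.7-fold). In all, limma called 2582 genes higher and 3750 lower, 1916 and 2595 of them changed at least 2-fold, and 509 of the calls were at background in 1 group. The count was 653 and 2358 without HP1α enzalutamide arrays 1 and 2 and 2705 without HP1α array 1 in complete medium. Without HP1α enzalutamide array 1 the calls of ENO2 (1.80) and CBX1 (−1.33) were lost, and that of CBX3 without either HP1α enzalutamide array (−2.01 and −2.11), without HP1α array 1 in complete medium (−1.45) and under quantile normalization (−1.35). The KLK3 call was lost with all 13 arrays in 1 fit.

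Of the lists in HP1α cells in enzalutamide medium, androgen-induced genes fell in 24 of 34 and rose in 0 (median −1.74; camera adjusted p = 1.60e-08; adjusted p = 0.126 with an estimated correlation; 25 adjusted over the list alone). CENPN (−3.58 ± 0.35), HOMER2 (−2.52 ± 0.19) and C1orf116 (−3.27 ± 0.32) were examples. Protocadherins rose in 18 of 37 and fell in 0 (median 0.96; adjusted p = 1.60e-08; adjusted p = 0.337 with an estimated correlation; 26 adjusted over the list alone). p53 targets fell in 10 of 23 and rose in 1 (adjusted p = 0.00188; adjusted p = 0.353 with an estimated correlation; 15 and 1 adjusted over the list alone). CCNG1 fell by 1.93 ± 0.20. ATF4 genes fell in 11 of 21 (adjusted p = 0.00432; adjusted p = 0.339 with an estimated correlation; 11 adjusted over the list alone), and hypoxia genes fell in 9 of 18 (adjusted p = 0.00830; adjusted p = 0.236 with an estimated correlation; 9 adjusted over the list alone). HK2, a glycolytic kinase gene, fell by 2.65 ± 0.21. REST-repressed genes rose in 6 of 20 and fell in 1 (adjusted p = 0.00810; adjusted p = 0.353 with an estimated correlation; 7 and 1 adjusted over the list alone). KIF1A rose by 1.43 ± 0.18. Neuroendocrine markers rose in 7 of 19 and fell in 1 (median 0.55; adjusted p = 0.0168; adjusted p = 0.236 with an estimated correlation; 7 and 1 adjusted over the list alone). Fibroblast markers rose in 4 of 7 (adjusted p = 0.0238; 4 adjusted over the list alone), basal markers in 4 of 11 (adjusted p = 0.0279; 6 adjusted over the list alone) and androgen-repressed genes in 2 of 5 (adjusted p = 0.0457; 2 adjusted over the list alone), with adjusted p = 0.236, 0.236 and 0.337 with an estimated correlation. Luminal markers fell in 5 of 17 and rose in 3 (adjusted p = 0.0903; 5 and 3 adjusted over the list alone) and mesenchymal markers rose in 6 of 16 and fell in 2 (adjusted p = 0.110; 6 and 3 adjusted over the list alone). Neither list was called, and FN1 rose by 3.52 ± 0.39. The other lists were not called (adjusted p from 0.118 to 0.964), with 0 mitosis, replication or cholesterol synthesis genes past the threshold over all genes or adjusted over the list alone. Adjusted over the list alone, 16 zinc finger genes rose and 23 fell, as did 3 and 1 interferon-stimulated genes, 2 and 7 cancer-testis genes, 0 and 1 heterochromatin factors, and 3 and 2 leukocyte and endothelial markers. The REST-repressed call was lost without HP1α array 1 in complete medium (median 0.46) and the fibroblast call without HP1α enzalutamide array 2 (median 1.1) and with only the groups compared (1.03). The androgen-repressed call was lost without HP1α array 1 in complete medium (0.37), either control enzalutamide array (0.59 each) or HP1α enzalutamide array 2 (0.44), and with all 13 arrays in 1 fit. The neuroendocrine call was lost under quantile normalization, with slide row as a block and with the filter on every array, where its median was −0.10, and the basal call under quantile normalization. Under normexp correction the medians of fibroblast markers, REST-repressed genes, neuroendocrine markers and basal markers were 0.321, 0.397, 0.214 and 0.374 (1.36, 0.804, 0.555 and 0.741 in the main fit), and these calls held.

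**Figure D3:**
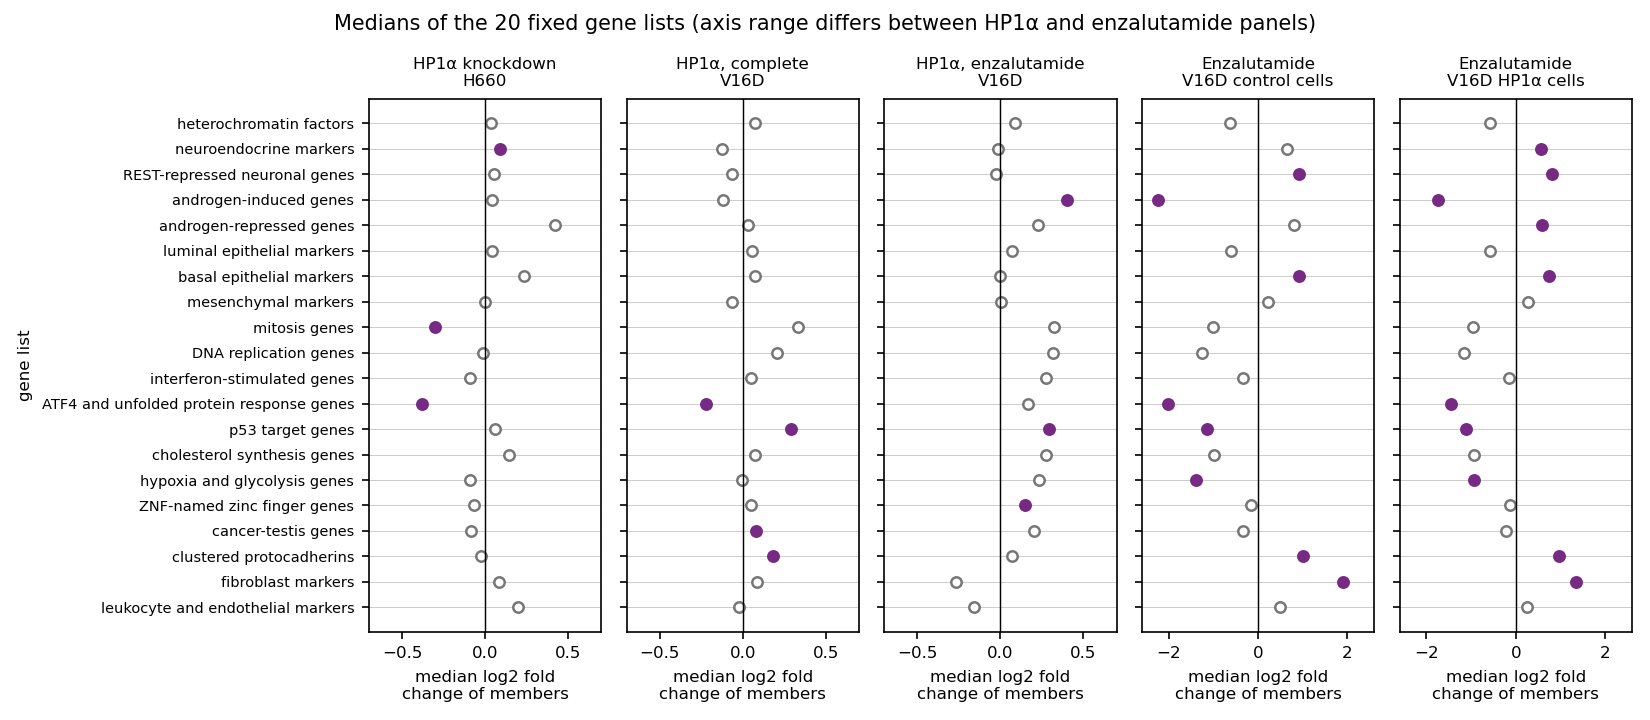
Median log2 fold change (x) of the 20 gene lists (y) in 5 comparisons, filled purple where camera with the preset correlation gave an adjusted p under 0.05 and open where not, with wider axes for enzalutamide. Androgen-induced genes have the lowest median in control-vector cells in enzalutamide medium (−2.25) and a positive one when HP1α and control vectors are compared in that medium (0.40).

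The 2 responses to enzalutamide medium, which share no arrays, ran alike across genes (Pearson r = 0.933, covariance 1.15; genes are not independent replicates). They shared 2268 higher and 3575 lower calls, where 483 and 971 were expected of independent lists, and 0 genes were called in opposite directions. Among genes called in control-vector cells, the slope of the response of HP1α cells on that of control cells was 0.844.

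**Figure D4:**
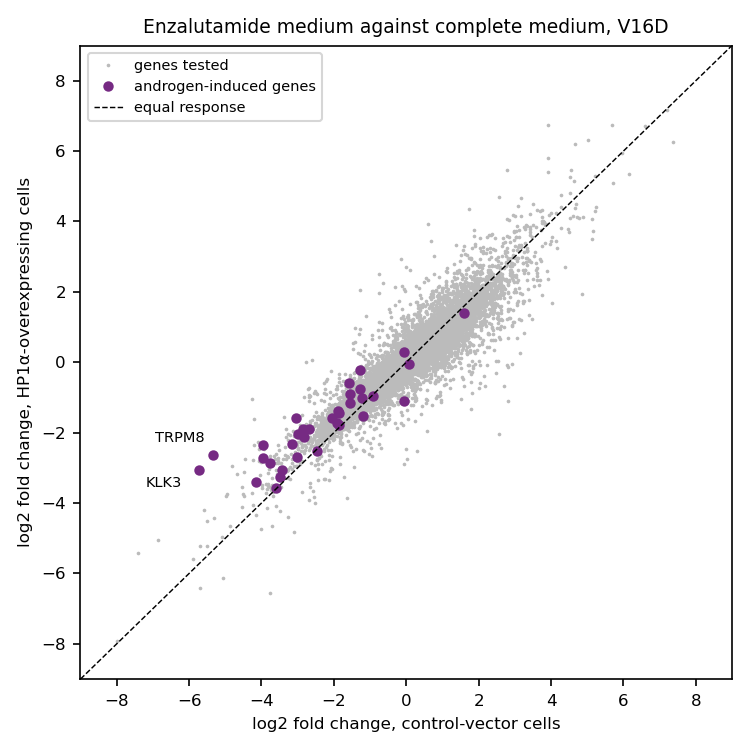
Log2 fold change in enzalutamide against complete medium in control-vector cells (x) and HP1α cells (y) for each gene tested (grey) and for androgen-induced genes (purple), with a dashed line for equal responses. KLK3 (−5.72 and −3.07) and TRPM8 (−5.33 and −2.62) lie above the line.

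Within enzalutamide medium, HP1α cells were compared with control-vector cells to ask whether HP1α alters cells under antiandrogen treatment. KLK3 read 5.17-fold higher in HP1α cells (2.37 ± 0.36, n = 2 against 2; adjusted p = 0.421), TRPM8 2.29 ± 0.31 and TMPRSS2 0.58 ± 0.34, none past the threshold. NCAM1 read 2.19 ± 0.43 (adjusted p = 0.698), on the 1 of its 3 probes that was above background in V16D cells. ENO2 (−0.20 ± 0.26), REST (−0.09 ± 0.30), EZH2 (0.08 ± 0.68), CBX1 (0.40 ± 0.19) and CBX3 (0.41 ± 0.52) did not pass. Chosen after their values were seen, BRINP1 (3.58 ± 0.39), a neural gene, IGFBP3 (2.78 ± 0.41) and ATOH8 (2.53 ± 0.67), a bHLH factor gene, were among the largest positive differences. limma called 0 of 18147 genes, and 931 had an unadjusted p under 0.05 (574 higher, 357 lower). Those were 5.13% of the genes tested, near the share of 0.05 that no change would give. With replicate number as a block within each medium the counts were 0 and 3613. Both control arrays in this medium lay in the first row of the slide and both HP1α arrays in the second, and with slide row as a block the count was 1586. The count was 25 with only the groups compared and 11 with all 13 arrays in 1 fit, 10 without control enzalutamide array 2, 8 without HP1α enzalutamide array 1 and 2 without either control array in complete medium.

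As a list, androgen-induced genes were higher in HP1α cells in enzalutamide medium, with 29 of 34 positive (median 0.40; camera adjusted p = 5.90e-06; adjusted p = 0.236 with an estimated correlation), among them PMEPA1 (1.75 ± 0.43) and HERC3 (1.06 ± 0.25). Over all genes 0 members passed, and 4 did adjusted over the list alone. Leaving out any 1 array kept the call, with medians of 0.40 to 0.45, and with slide row as a block the median was 0.55. That block takes the row effect from the complete-medium arrays, where row coincided with array number. p53 targets were called higher (19 of 23 positive, median 0.29, adjusted p = 0.00253; adjusted p = 0.715 with an estimated correlation; 0 adjusted over the list alone). CDKN1A read 1.26 without passing. Zinc finger genes were called higher (324 of 474 positive, median 0.15, adjusted p = 0.00314; adjusted p = 0.715 with an estimated correlation; 0 adjusted over the list alone). ZNF208 read 1.60 without passing. The other lists were not called (adjusted p from 0.144 to 0.955), neuroendocrine markers among them (median −0.02; adjusted p = 0.955; 2 higher adjusted over the list alone), and of cancer-testis genes 2 were higher and 1 lower and of hypoxia genes 1 higher adjusted over the list alone. With replicate number as a block within each medium, 4 of these lists were called higher, mitosis and DNA replication genes (median 0.32 each; adjusted p = 0.000216 each), cholesterol synthesis genes (0.27; adjusted p = 0.0189) and interferon-stimulated genes (0.27; adjusted p = 0.0490). An estimated correlation was not run with that block, and in the main fit camera with it gave these 4 lists adjusted p from 0.936 to 0.965. The p53 call was lost without control enzalutamide array 1 (median 0.30) and the zinc finger call without control enzalutamide array 2 or HP1α enzalutamide array 1 (0.08 each), and both were lost with slide row as a block (−0.09 and 0.05).

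The difference between the effects of HP1α in the 2 media tested whether medium altered them. Androgen-induced genes shifted up, with 28 of 34 positive (median 0.48; camera adjusted p = 1.65e-08; adjusted p = 0.125 with an estimated correlation). The differences were 2.71 ± 0.44 for TRPM8, 2.65 ± 0.52 for KLK3 and 1.47 ± 0.35 for HERC3, and 2 members passed adjusted over the list alone. Leaving out any 1 array kept that call, with medians of 0.37 to 0.66. ATF4 genes were called higher (18 of 21 positive, median 0.54, adjusted p = 0.0101; adjusted p = 0.551 with an estimated correlation; 0 adjusted over the list alone). TMPRSS2 (0.90 ± 0.48), ENO2 (0.33 ± 0.37), REST (−0.05 ± 0.43), EZH2 (0.09 ± 0.97), CBX5 (0.25 ± 0.34), CBX1 (0.33 ± 0.27) and CBX3 (0.14 ± 0.73) did not pass, and NCAM1 was at background in complete medium. limma called 0 genes, and 323 had an unadjusted p under 0.05 (146 higher, 177 lower). Those were 1.78% of the genes tested, below the share of 0.05 that no change would give. With replicate number as a block within each medium the counts were 0 and 1315. The other lists were not called (adjusted p from 0.103 to 0.946), and in 2 of them, cancer-testis genes and leukocyte and endothelial markers, 1 member each was lower adjusted over the list alone. The ATF4 call was lost without control array 2 (median 0.40) or HP1α array 1 (−0.02) in complete medium, without control enzalutamide array 2 (0.46) or HP1α enzalutamide array 2 (0.25), and with slide row as a block (−0.15). With that block 452 genes were called, 14 were without HP1α array 1 and 3 without control array 2 in complete medium, and 1 was with all 13 arrays in 1 fit.

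Across genes the effects of HP1α in the 2 media ran partly alike (Pearson r = 0.321, 63.6% of signs shared). The effects of knockdown in NCI-H660 and of raised HP1α in V16D cells, compared over 17071 genes, showed r = 0.00938 in complete medium, with 48.0% of signs shared, and r = −0.0987 in enzalutamide medium, with 42.6% shared.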

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

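All tests of explanations in this part were chosen after the result they concern had been seen. The effect of HP1α on androgen-induced genes differed between media (median of the difference 0.48, camera adjusted p = 1.65e-08, adjusted p = 0.125 with an estimated correlation), as did its effect on ATF4 and unfolded protein response genes (median 0.54, adjusted p = 0.0101, adjusted p = 0.551 with an estimated correlation). The ATF4 difference was lost when any 1 of 4 arrays was left out (medians −0.02 to 0.46). A signal also appeared in control spots that no comparison used. The spike-in control probe E1A_r60_1 had a mean signal of 2.63e+05 over the V16D arrays, and group means of 1.74 in NCI-H660 control and 2.31 in knockdown arrays.

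Androgen-induced genes stood higher in HP1α than in control-vector cells in enzalutamide medium, where both control arrays lay in the first slide row and both HP1α arrays in the second. A row effect would raise the same genes in the second row in complete medium, where each vector had 1 array in each row, but their median difference there was −0.19. A weaker response of all genes to enzalutamide medium was set against the slope of 0.844 between the responses. After that slope was taken out, the 27 androgen-induced genes that fell had a median residual of 0.21, at percentile 99.95 of 10000 lists of genes with like falls (the middle 95% of them ended at 0.12). The residual was above 0 in 18 of the 27, and the others did not go that way. Genes of the random lists were matched on their fall alone and need not vary together, as androgen-induced genes may. The percentile thus does not exclude a shift that androgen-induced genes share between these few arrays. HP1α may limit the fall of androgen-induced genes under blockade more than that of other genes, a hypothesis found and tested on the same arrays. Slide row stays open, and a difference between the cultures, such as in the dose that reached them, was not tested.

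The complete-medium arrays numbered 1 and 2 differed alike with both vectors. Their numbers follow the slide row, but over the 1937 genes that differed at least 2-fold alike with both vectors, the difference between rows in enzalutamide medium had a slope of −0.084 (95% interval −0.099 to −0.067) on that in complete medium, against the 0.5 or more a row effect would need. Row and vector coincided in enzalutamide medium, so that slope assumes that the vector did not offset a row effect. Its interval came from resampling genes, which are not independent, and does not measure the spread between arrays. Dimmer arrays would shift genes by their level, but with a trend on level taken out the differences with the 2 vectors still correlated at 0.79 across genes (0.791 before). The mitosis genes were lower by a median of −3.99 on arrays 2, but the pattern was found on that list, so the value does not test whether the cultures were collected in another growth state. That explanation stays open, as the labels give no detail on it.

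KLK3 was above background on knockdown arrays 2 and 3 alone. A trace of RNA from V16D or a like cell could give such a level, 0.0283% of that in V16D cells on array 2. At that share, 22 of the 24 genes abundant in V16D and not above background in NCI-H660 controls would lie below −5.36 on array 2, as did 95% of the dim genes there. The Spearman correlation of their rise with their V16D level (0.25) could therefore hardly be high and decides nothing. Androgen signalling raised by the knockdown could be a second source, but the other 30 androgen-induced genes had a median change of 0.13 on array 2 and went both ways, which decides nothing either, so the explanations cannot be told apart.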

How the results depend on the processing

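Slide row as a block, replicate number as a block within each medium, averaged NCI-H660 controls and leaving out both complete-medium arrays of 1 number were chosen after seeing the data. Where no reason is given, the cause was not tested. The limma count of 0 in the knockdown (2405 at an unadjusted p under 0.05) held under all alternatives run. The counts for enzalutamide medium (8096 and 6332) stayed within 1.5 times under every alternative but the leave-outs, between 6308 and 10728 with the control and between 4406 and 8311 with the HP1α vector. The 4 androgen-induced calls held in all alternatives but the estimated correlation. With an estimated correlation, 0 of 30 list calls held. Of the single gene values, 10913 kept their side of the threshold, with direction kept where called and within 1 SE of the main fit where not. A call was lost by 259 and gained by 150, 613 uncalled values moved by more than 1 SE, and 11 reversed. Of the list values, 2313 kept their side of the threshold, 83 lost and 134 gained a call and 28 reversed. Reversals were counted only where at least 1 of the 2 fits made a call, so turns of direction among uncalled genes and lists are not included.

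The count for raised HP1α in complete medium (3) was 1 under normexp correction and with the mean of all probes, 5 under quantile normalization and with the deposited table, 0 with no filter and with only the groups compared, and 11 with all 13 arrays in 1 fit. The count for HP1α in enzalutamide medium (0) was 11 with all 13 arrays and 25 with only the groups compared, and that for the difference of effects (0) was 1 with all 13 arrays. With replicate number as a block the first count was 0, and as a block within each medium it was 5, with 15 lists called in place of 9. The 6 gained calls, all at the preset correlation, were higher mitosis and DNA replication genes with HP1α in both media, and cholesterol synthesis and interferon-stimulated genes in enzalutamide medium. Same-numbered arrays deviated alike in complete (r across genes 0.791) and enzalutamide medium (0.416), but not across media (−0.0405 to 0.00348) or in NCI-H660 (0.0235 and 0.0292), so a deviation shared within a medium stays in the residual spread of the main fit. With the block within each medium, genes at an unadjusted p under 0.05 were 1416 for HP1α in complete medium (325 in the main fit), 3613 in enzalutamide medium (931) and 1315 for the difference (323).

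With slide row as a block, the counts for HP1α were 6 in complete and 1586 in enzalutamide medium and 452 for their difference, with 45 lists called in place of 27. That block takes the difference between complete-medium arrays 1 and 2, which lay in separate rows, for a row effect in both media. It turned the medians of p53 targets (−0.093) and protocadherins (−0.47) for HP1α in enzalutamide medium, of mitosis genes in enzalutamide medium in HP1α cells (1.06), and of mitosis (4.02), ATF4 (−0.15) and p53 genes (−0.44) in the difference, where CENPF read 3.46.

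Without array 1 of both complete-medium groups, the HP1α counts were 59 in complete and 5 in enzalutamide medium and 29 for the difference, and the mitosis median turned to 1.11 in control and 0.96 in HP1α cells in enzalutamide medium. Without array 2 of both they were 27, 5 and 3, 49 lists were called, and the mitosis median of the difference was 0.27. VWF turned with its brightest probe, to 0.81 and 0.85 in enzalutamide medium with the control and HP1α vectors with all 13 arrays, 0.73 and 0.75 without arrays 1, and 0.89 and 0.95 without arrays 2.

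Leaving out 1 array assumes that a lone array varies like the other groups. It gave counts of 0 to 43 for HP1α in complete and 0 to 10 in enzalutamide medium, 0 to 14 for the difference, 4637 to 8047 and 653 to 6396 for enzalutamide medium in control and HP1α cells, 2 to 5 lists in NCI-H660 (3 with all arrays) and 24 to 44 in V16D cells (27 with all arrays). VWF ranged from −3.13 to 0.81 in control and from −2.59 to 0.85 in HP1α cells. For HP1α in complete medium, medians ran from −0.28 to 0.42 for heterochromatin factors, −1.76 to 2.54 for mitosis, −1.14 to 1.49 for replication, −0.29 to 0.41 for interferon, −0.72 to 0.28 for ATF4 and −0.41 to 0.72 for cholesterol synthesis genes, and −0.12 to 0.54 for protocadherins. For enzalutamide medium in control cells the mitosis median ran from −3.04 to 1.11. For the difference, medians ran from −0.28 to 0.41 for heterochromatin factors, −2.15 to 2.15 for mitosis, −1.15 to 1.38 for replication and −0.42 to 0.61 for cholesterol synthesis genes.

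Slide as a block was not run, since each slide held 1 line. The normexp alternative used the median spot signal because the files lack the mean. Leaving out genes abundant in V16D from the knockdown removed no tested gene and so tested nothing. Genes near background limit the precision of fold changes, as 553 and 509 of the enzalutamide calls were at background in 1 group.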

Other observations

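No explanation is tested in this part, and genes that did not pass the test were chosen after their values were seen. Some of the largest changes in enzalutamide medium were in genes outside the lists. In control-vector cells SLIT1, an axon guidance gene, rose by 5.72 ± 0.70 and SDK2, a synaptic adhesion gene, by 7.21 ± 1.03, and STAC rose by 5.96 ± 0.47. In HP1α cells SDK2 rose at least 51.6-fold and TENM2, another synaptic adhesion gene, by 6.31 ± 0.94, calls lost without HP1α enzalutamide array 1 (6.10 for TENM2). TMEFF2, a prostate and brain transmembrane gene, fell by 5.90 ± 0.76 in control-vector cells and fell by 5.58 ± 0.76 in HP1α cells. ADH1A, an alcohol dehydrogenase gene, fell at least 49.4-fold in HP1α cells. None of these genes passed the test of the difference between the vectors, where limma called 0 genes, with 323 at an unadjusted p under 0.05.

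Other genes stood apart without passing the test over all genes. In enzalutamide medium the neural transcription factor genes POU3F2 (1.30 ± 0.23) and ONECUT2 (0.69 ± 0.19) and the oxygen sensor gene EGLN3 (1.41 ± 0.30) read higher in HP1α than in control-vector cells, and APOC1 (−1.44 ± 0.36), an apolipoprotein gene, read lower. In the NCI-H660 knockdown TMEFF2 (1.33 ± 0.27), SCGN (1.53 ± 0.30), which encodes a calcium-binding protein of neuroendocrine cells, and TNFRSF11B (1.49 ± 0.14), encoding osteoprotegerin, read higher than in control cells.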
